A study of Homo sapiens with 4 samples.

How the data were processed

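Gene expression was measured on Affymetrix human oligonucleotide arrays (platform per the probe annotation) in total RNA of RWPE1 and RWPE2 cells, with 1 untreated and 1 lunasin-treated culture of each line. The values used are probe set intensities on a linear scale, as the authors deposited them, made with RMA per the submitters' processing notes. The RMA version, background settings and the scanning steps are not given in the sources used here. RMA writes log2 values, and the deposited intensities lie between 7.88 and 14230, with array medians of 69.9 to 71.5, so they had been raised back to the linear scale. The quartiles of the 4 arrays lie close together, as they do after a normalization that gives arrays a common distribution. Such a step sets an overall difference in RNA content per cell to near 0, and it cannot be recovered from these values.

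The intensities were taken to log2 with no added constant. Of 22283 probe sets, 68 are array controls and were left out of all gene comparisons. A single gene symbol was given for 19065 probe sets, several for 1043, and 2107 are not listed in the annotation used here. Symbols were brought up to date through the gene ID in the RefSeq gene table of assembly GRCh38.p14, used for names alone, for 19053 of the single-gene probe sets, and 12 kept the older symbol. No coordinates are given because the sources used here name no build. For each of 11963 genes the probe set with the highest mean log2 value over the 4 arrays stood for the gene. Genes with a mean at or above the median of these probe sets, an intensity of 93.9, were kept, which left 5982 genes.

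With 1 array per group, the lunasin difference in each line, the difference between the untreated lines and the difference between the responses of the lines (RWPE1 minus RWPE2) are log2 differences between arrays, with no replicate check and no p-value. Genes at least 2-fold apart were counted. A model with a term for line and a term for treatment was fitted to all 4 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and Benjamini-Hochberg adjustment over the 5982 genes. It tests the treatment effect common to the 2 lines and the line effect common to untreated and treated cells, with 1 residual degree of freedom and 6.66 prior degrees of freedom. In that model the lines pair the treated and untreated cultures. Its p-values take the 2 lines, or the 2 treatments, as replicates, so they measure the spread between these arrays, and a response that differs between the lines counts as error. The labels do not say whether cultures were grown or arrays run on separate days. The number of arrays limits the precision of every value.

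Gene lists, 35 in all, were fixed for processes and marker classes that suit prostate epithelium, oncogenic transformation and a chemopreventive peptide, including markers of stromal, blood, endothelial and neuroendocrine cells. For each list with at least 5 kept members, its median difference was ranked among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list is said to stand apart when its percentile lies under 2.5 or over 97.5, which describes these arrays and is no test across cultures. For 32 lists, 1.6 are expected to stand apart by chance in each comparison. Members passing the limma test are counted over all genes and also adjusted over the list alone. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

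The genes named are, in each of the untreated line comparison, the lunasin comparisons and the difference between the responses, up to 12 with the largest positive and 12 with the largest negative log2 difference, if at least 2-fold. For the common lunasin effect they are the 10 in each direction with the largest smaller change among genes that went the same way in both lines. For each list they are up to 4 members with the largest difference. HRAS was added for its level, and some items the rule covers are not reported here. Groups, tests, this rule, the lists and all but 1 of the alternatives were fixed before the data were examined. The alternatives were quantile, common-median and cyclic loess normalization, no filter or an upper-quartile filter, the median over a gene's probe sets, probe sets with an s or x suffix left out, log2 of the intensity plus 16, a 1.5-fold threshold, limma without the blocking term and limma-trend. The treated pair in place of the untreated pair was added after the data had been seen.

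The limma model was tested on simulated data, and the ranking of lists on lists drawn at random from the real genes. For the common lunasin effect, with 200 of 5982 genes changed by 0.5 or 1.0 on the log2 scale in both lines and a noise SD of 0.06 per array, the limma model recovered 100% of changed genes at either size and called 8 unchanged genes. That noise, taken from the RWPE2 pair, is smaller than the spread in the real fit. With gene variances drawn from the real fit, a median SD of 0.14 per array, the model recovered 8% of genes changed by 0.5 and 93% of those changed by 1.0, and called 3 unchanged genes. For the lunasin comparison in RWPE1, 6.0% of 200 random lists of 24 genes stood apart without a shift, and 99.0% did with a shift of 0.3. These lists came from the random lists they were ranked among, and the shift was added to their medians. Both shares are thus largely set by the procedure, and they give no error rate for lists whose genes move together.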

Results

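Expression was profiled in 2 related human prostate epithelial cell lines to find out which genes, tumour suppressors among them, respond to lunasin, a peptide from soybean seed. RWPE1 cells are non-tumorigenic epithelial cells immortalized with human papillomavirus. RWPE2 cells were derived from RWPE1 by transformation with an oncogene and form tumours. Each line was grown untreated or with 2 microM lunasin for 24 hr, and each of the 4 conditions was measured on 1 array, so differences between single arrays have no replicate error. Over the 5982 genes kept, the SD of the log2 difference between treated and untreated cells was 0.31 in RWPE1 and 0.10 in RWPE2, against 0.55 between the untreated lines.

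In RWPE1 cells, the genes with the largest differences were all higher with lunasin. TPR, a component of the nuclear pore basket, was 3.14-fold higher (intensity 128.1 against 40.7), a log2 difference of 1.65, while its other probe sets gave 0.38 and 0.071. KTN1, which encodes the kinesin-binding protein kinectin, was 2.97-fold higher, and DICER1, the ribonuclease that makes microRNAs, was 2.72-fold higher. GJA1, the gap junction protein connexin 43, was 2.58-fold higher and PSMC6, an ATPase of the proteasome, 2.58-fold higher. TOB1, an antiproliferative gene of the tumour suppressor list, was 2.32-fold higher, with an intensity of 112.2 against 48.3.

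The other genes among the 12 with the largest differences were ZNF146 (log2 difference 1.44), the spindle pole gene ASPM (1.27), the kinase PKN2 (1.22), the chromatin protein HMGB2 (1.22), the lipid-binding protein OSBPL8 (1.21) and the metalloproteinase ADAM9 (1.21). In all, 48 genes were at least 2-fold higher with lunasin and 0 were at least 2-fold lower, and at 1.5-fold the counts were 433 and 0. The 48 became 22 with 16 added to the intensities and 16 with the upper-quartile filter. Probe sets did not always go together: 3 of 6 probe sets of DICER1 and 2 of 3 of PKN2 were higher, and the median over the probe sets of DICER1 was 0.33. The untreated RWPE1 array also had the brightest 18S ribosomal RNA control probe set, with an intensity of 169.7 against 117.8 to 132.3 on the others.

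Gene groups that stood apart in RWPE1 were those of RNA splicing, cell junctions, chaperones, the mitotic spindle and inflammation. Of 37 splicing factors, 28 were above 0 (median log2 difference 0.24, percentile 99.99), with LUC7L3 at 1.02, HNRNPR at 0.86 and HNRNPA2B1 at 0.78. Of 17 genes of desmosomes and adherens junctions, which hold epithelial cells together, 12 were above 0 (median 0.24, percentile 99.8), including DSP at 0.96, DSG3 at 0.69 and DSC3 at 0.61. Of 24 spindle checkpoint and mitotic kinase genes, 17 were above 0 (median 0.11, percentile 97.6), led by BUB1B at 1.16 and MAD2L1 at 1.08, checkpoint proteins that delay anaphase, and the kinetochore genes CENPE and CENPF, both at 0.69. Heat shock and chaperone genes had a median of 0.15 (percentile 97.9), with HSP90AA1 at 0.71 and DNAJA1 at 0.57. The NF-kB and inflammatory cytokine list was lower (median -0.17, percentile 1.91), although IL1A was at 0.45 and S100A8 at 0.36. In all 5 of 32 lists stood apart, where 1.6 are expected. All 5 use the untreated RWPE1 array, so a response to lunasin cannot be told apart from a deviation of that array. For RWPE2 minus RWPE1, the untreated and treated pairs gave medians of 0.06 and -0.09 for splicing and 0.29 and 0.04 for desmosomes. They gave 0.15 and -0.12 for the spindle, -0.18 and -0.23 for chaperones and -0.44 and -0.27 for inflammatory genes. Of the 5 lists only the splicing list stood apart under every alternative run. The chaperone list did not under 5 of 8 alternatives (percentiles from 94.9 to 97.49) nor the inflammatory list under 5 (from 2.69 to 79.2, with its sign turned under the upper-quartile filter), and the call was lost for the spindle list with the upper-quartile filter (89.3) and the median over probe sets (96.7), and for the desmosome list with s and x probe sets left out (95.4).

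Tumour suppressors as a group did not stand apart in RWPE1, with 15 of 28 above 0 and a median of 0.03 (percentile 92.1). Members with the largest differences were TOB1 at 1.22, the atypical cadherin FAT1 at 0.90, the transcription factor KLF6 at 0.88 and the serpin SERPINB5, also called maspin, at 0.66. Pro-apoptotic genes had a median of -0.15 (percentile 3.24), with cytochrome c (CYCS) at 0.60 and BAD at -0.47. Histone acetyltransferases and deacetylases, which act on the core histones that lunasin is known to bind, had a median of -0.10 (percentile 18.1), with HDAC2 at 0.71. Core and linker histones had a median of -0.09 (percentile 28.04). DNA repair genes had a median of -0.01 (percentile 78.8), a value that was above 0 after a shift to a common median or cyclic loess.

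In RWPE2 cells, COL5A1, a chain of fibrillar collagen type V, was 2.15-fold higher with lunasin (intensity 350.9 against 163.3), and its other probe sets gave 0.21 and 0.16. It was the only gene at least 2-fold apart of the 5982 compared, and 0 were lower, and it fell to 0.67 with the median over probe sets and 0.21 with s and x probe sets left out, while the upper-quartile filter removed it. Small shifts ran through several groups. Of 19 keratinocyte differentiation genes, 17 were above 0 (median 0.16, percentile 100), including the cornified envelope precursors SPRR3 at 0.36, SPRR1A at 0.35 and IVL at 0.29, and the keratin KRT13 at 0.25.

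Other groups that stood higher in RWPE2 were the extracellular matrix (median 0.09, 19 of 24 above 0), NF-kB and inflammatory genes (0.08, 11 of 15), cholesterol synthesis (0.06, 16 of 21), integrins (0.06, 12 of 17) and desmosomes and adherens junctions (0.05, 13 of 17). HMGCS1, which encodes an early enzyme of the mevalonate pathway, was at 0.32 and the desaturase FADS2 at 0.30, and the calcium-binding S100A8 and S100A9 were at 0.25 and 0.24. Ribosomal protein genes were lower by a small amount, with 11 of 43 above 0 (median -0.03, percentile 0.180). Tumour suppressors had a median of 0.04 (percentile 96.2) and pro-apoptotic genes of 0.05 (percentile 96.3). These lists too rest on 1 array per condition, so a response to lunasin cannot be told apart from a deviation of either RWPE2 array. Only the keratinocyte and matrix lists stood apart under every alternative run. The call was lost under at least 1 alternative for desmosomes (lowest percentile 94.4), integrins (94.5), inflammatory genes (89.99 without a filter), cholesterol synthesis (59.4 with s and x probe sets left out) and ribosomal proteins (3.31 with s and x probe sets left out).

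Across genes, which are not independent replicates, the Pearson correlation of the 2 responses was 0.05 and the Spearman correlation 0.08, and 52.3% of genes had the same sign. The RWPE2 differences are small, which lowers any correlation: 2 probe sets of a gene had a correlation of 0.21 in RWPE2 and of 0.66 in RWPE1 across 1576 genes. In a comparison chosen after the data had been seen, 1 probe set in RWPE1 and the other in RWPE2 had a correlation of 0.0052. The values within the lines would put it at 0.38 if the lines shared a single response and nothing else moved both probe sets. The 2 probe sets share arrays, so a deviation of 1 culture or array also makes them alike. The comparison therefore cannot decide whether the lines share a response to lunasin. The desmosome list stood higher in both lines. The genes with the largest change in the same direction in both lines included BUB1B (1.16 in RWPE1 and 0.32 in RWPE2), the galactosyltransferase B4GALT1, the planar polarity gene VANGL1, the mannose 6-phosphate receptor IGF2R and involucrin (IVL). B4GALT1 rests on 1 probe set, as the other 3 were below 0 in RWPE2 and 1 of them in RWPE1 too, and the other IGF2R probe set gave 0.0075 and 0.089. Lower in both were the pseudokinase TRIB3 (intensity 726.6 against 970.4 in RWPE1 and 994.5 against 1329 in RWPE2), the nucleophosmin family member NPM3, the endosomal GTPase RAB5C, valyl-tRNA synthetase (VARS1), the mitochondrial enzyme PCK2 and the glutathione-degrading enzyme CHAC1, with the other VARS1 probe set at -0.33 and -0.056.

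For the effect common to both lines, limma called 0 genes at an adjusted p under 0.05, the lowest adjusted p being 0.916. At an unadjusted p under 0.05 it gave 178 genes, of which 164 were higher, where 299.1 are expected by chance. In data simulated with the gene variances of this fit, it recovered 8% of common changes of 0.5 and 93% of changes of 1.0 on the log2 scale. BUB1B had a common log2 effect of 0.74 (unadjusted p = 0.00561, adjusted p = 0.916) and TRIB3 of -0.42 (unadjusted p = 0.0101, adjusted p = 0.916), each in the same direction in both lines. In none of the lists did a member pass over all genes or adjusted over the list alone. Without the line term limma called 0 genes and gave 0 at an unadjusted p under 0.05, limma-trend called 0 and gave 195, and after quantile normalization limma called 21 genes, all higher, and gave 340. Those 21 had a median of 1.25 in RWPE1 and 0.12 in RWPE2, and 3 were below 0 in RWPE2, so RWPE1 carries most of these calls.

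The difference between the responses was at least 2-fold for 51 genes with the larger value in RWPE1 and for 1 gene, COL5A1 (-1.05), with the larger value in RWPE2. The 51 became 19 with the upper-quartile filter and 78 without a filter. The genes were led by DICER1 (1.58), KTN1 (1.56), TPR (1.55), PSMC6 (1.54), ZNF146 (1.53) and HMGB2 (1.30). The regulatory subunit of protein kinase A PRKAR1A (1.27), the thioredoxin-related TMX1 (1.26), the actin-binding twinfilin TWF1 (1.26), the kinesin KIF5B (1.26), the fatty acid elongation enzyme HACD2 (1.26) and LRBA (1.22) followed. Other probe sets gave 0.025 for KIF5B, 0.44 and 0.23 for TWF1, 0.54 for LRBA, 0.40 and 0.19 for TPR, 1.22 and 0.30 for PRKAR1A, and from -0.30 to 1.20 for DICER1. These differences rest on 1 array per condition and were not tested.

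**Figure D1:**
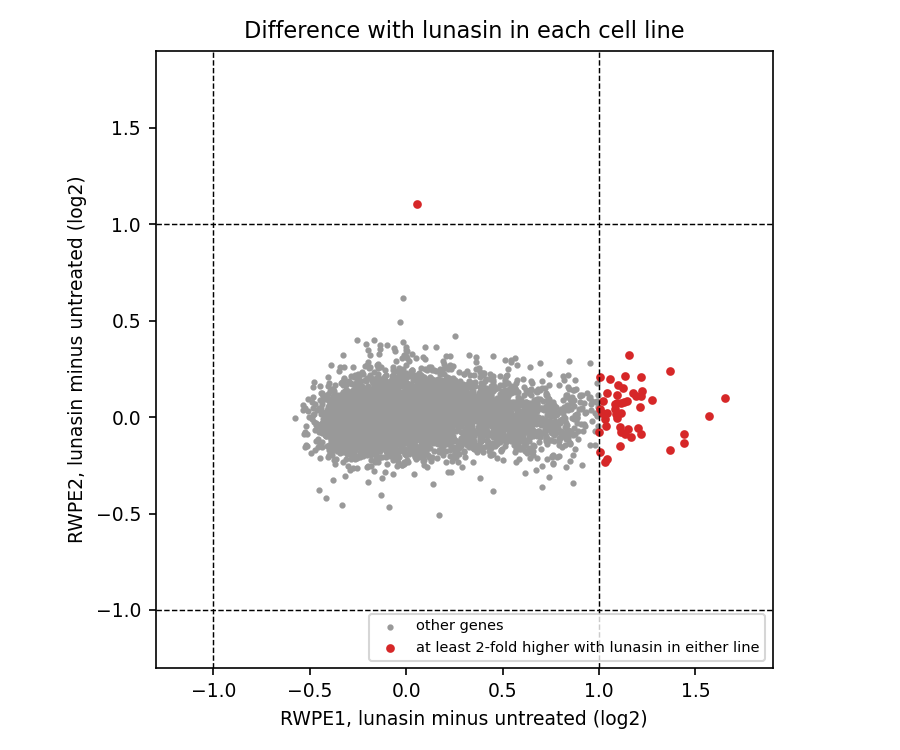
Each point is 1 of 5982 genes, with the log2 difference between lunasin-treated and untreated RWPE1 cells on the horizontal axis and that of RWPE2 cells on the vertical axis; dashed lines mark 2-fold. In RWPE1 48 genes lie at or past 2-fold higher and 0 past 2-fold lower, and in RWPE2 1 gene, COL5A1, lies past 2-fold.

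**Figure D2:**
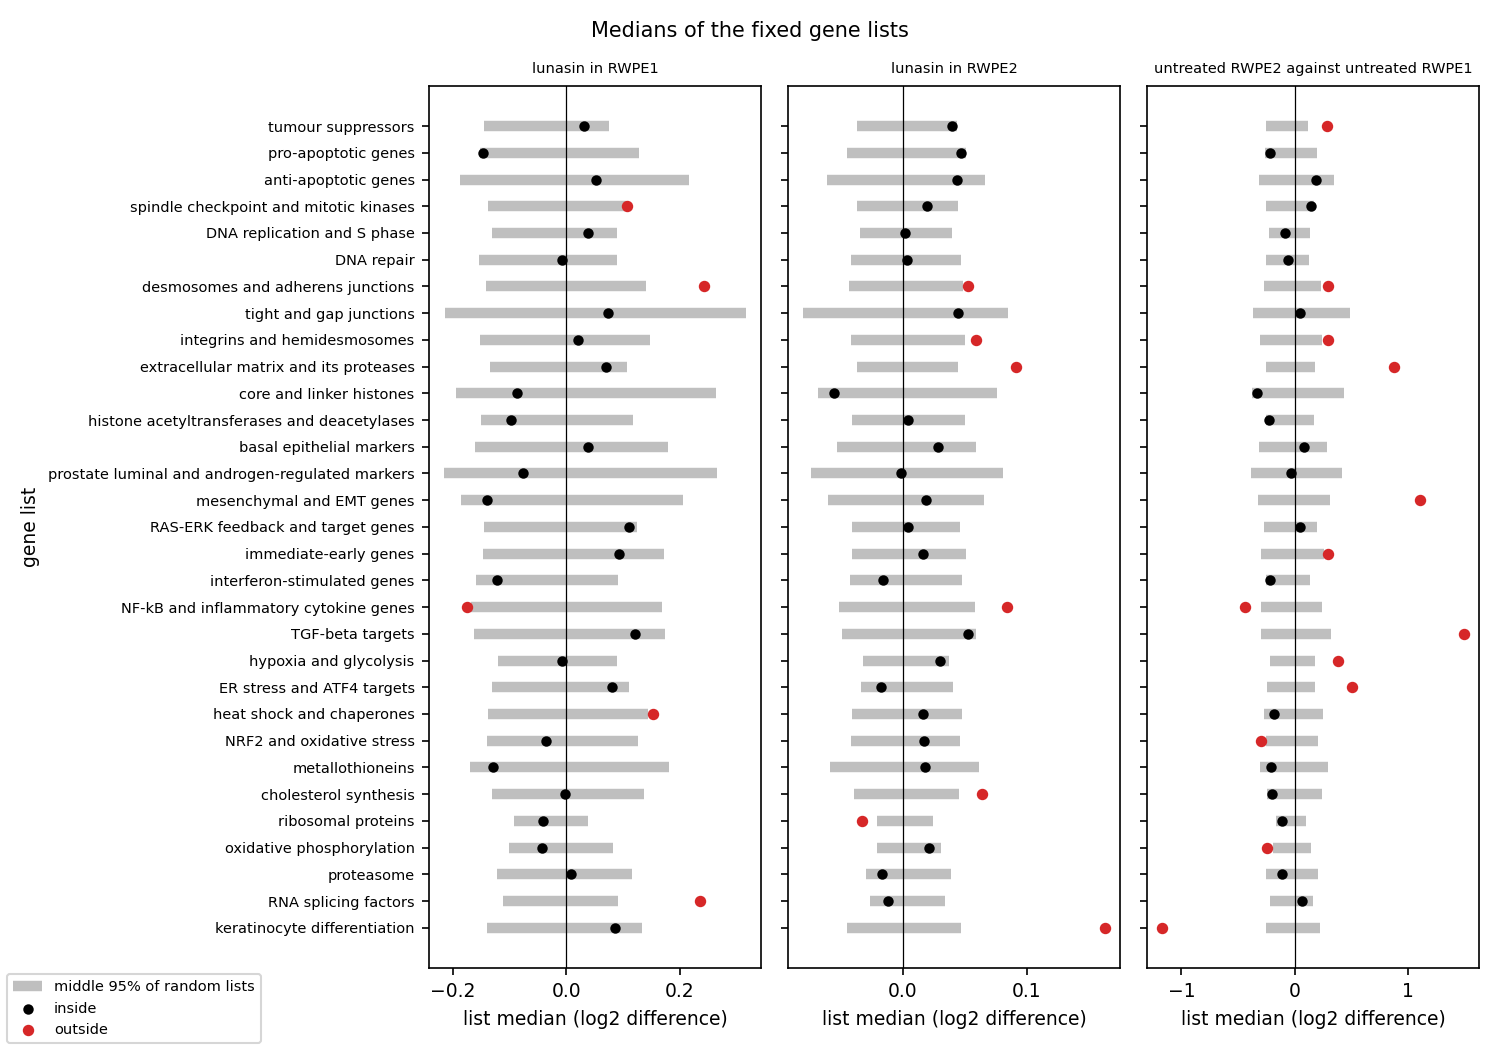
Median log2 difference of gene lists with at least 5 members (points; red where outside) beside the middle 95% of 10000 matched random lists (grey bars), for lunasin in RWPE1, lunasin in RWPE2 and untreated RWPE2 against untreated RWPE1, each panel with its own horizontal scale. The TGF-beta list lies at 1.49 and the keratinocyte differentiation list at -1.17 between the lines, while the highest list median with lunasin is 0.24.

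Genes of stratified epithelium were lower, and genes of the extracellular matrix higher, among those furthest apart between the lines. Keratin 13 (KRT13) had an intensity of 737.1 and 666.6 in untreated and treated RWPE1 cells and of 45.2 and 53.8 in RWPE2 cells, a line effect of -3.83 ± 0.14 on the log2 scale (SE, n = 2 arrays per line, limma adjusted p = 2.33e-05, lower in both pairs). Keratin 4 (KRT4, -2.83 ± 0.13), the calmodulin-like CALML3 (-2.84 ± 0.13), the cornified envelope gene SPRR1A (-2.49 ± 0.14) and the skin proteases KLK10 (-2.43 ± 0.12) and KLK5 (-2.44 ± 0.13) were lower in RWPE2 as well. Higher in RWPE2 were PLOD2, a collagen lysyl hydroxylase (3.26 ± 0.12, adjusted p = 2.33e-05), the collagen cross-linking oxidase LOXL2 (3.15 ± 0.13), and the matricellular growth factor CCN2 (2.92 ± 0.12). The matrix protein SPARC passed as well and was 7.89-fold higher in the untreated pair.

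Other genes with large line differences were the actin-binding caldesmon CALD1 (2.83 ± 0.20), TMEM158 (2.83 ± 0.15), known to be induced by RAS, the sulfate transporter SLC26A2 (2.31 ± 0.20), ADAM9 (2.24 ± 0.24), the hypoxia factor HIF1A (2.14 ± 0.23), TPR (1.99 ± 0.31) and KTN1 (1.80 ± 0.31), all passing the limma test, as did the focal adhesion gene FERMT2, 6.98-fold higher in the untreated pair. These effects average unlike pairs, with untreated and treated differences of 2.77 and 1.22 for TPR, 2.58 and 1.02 for KTN1, 2.67 and 1.60 for HIF1A and 2.82 and 1.66 for ADAM9. KRT16, GAL, LCN2, H2BC12, H2BC12L and the water channel AQP3 were lower in RWPE2, with line effects from -2.23 to -1.50, and passed as well. HRAS did not pass (0.23 ± 0.13, adjusted p = 0.225). In the untreated pair 320 genes were at least 2-fold higher and 64 lower in RWPE2, in the treated pair 136 and 58, and in both pairs 120 and 41, while the upper-quartile filter gave 176 and 38 in the untreated pair. The line effect passed an adjusted p under 0.05 for 750 genes higher and 567 lower in RWPE2, of which 188 and 56 were also at least 2-fold apart, with s and x probe sets left out 290 and 172 passed, with the upper-quartile filter 452 and 396, and with cyclic loess 804 and 373. CALML3 was at -0.12 in the untreated pair when probe sets with an s or x suffix were left out, and CALD1 at 0.34 and LOXL2 at 0.80 with the median over probe sets.

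**Figure D3:**
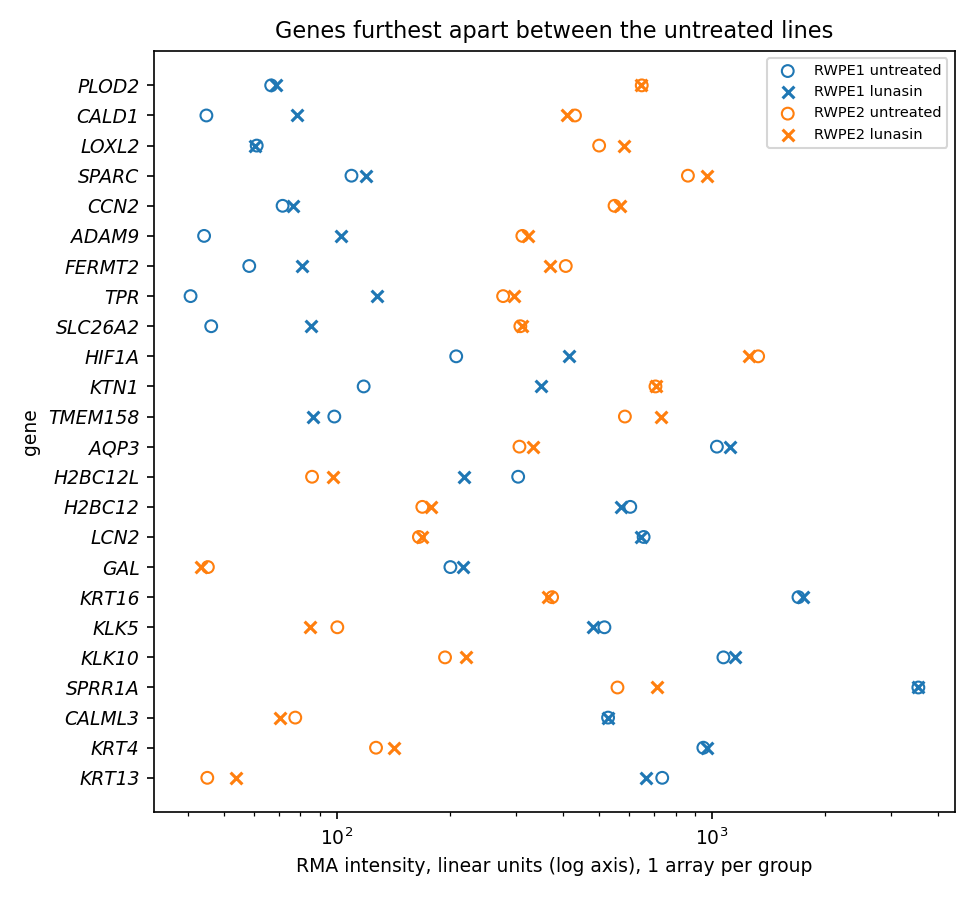
RMA intensities (linear units on a log axis) of the 24 genes furthest apart between the untreated lines, 1 array per symbol, with circles for untreated and crosses for lunasin-treated cells, blue for RWPE1 and orange for RWPE2. KRT13 lies at 737.1 and 666.6 in RWPE1 and at 45.2 and 53.8 in RWPE2, and TPR and KTN1 lie between the untreated RWPE1 value and the RWPE2 values in treated RWPE1 cells.

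By gene group, 16 of 19 keratinocyte differentiation genes were lower in RWPE2 by the limma test and 1 was higher (17 and 1 adjusted over the list alone), and the median in the untreated pair was -1.17 (percentile 0). Of 24 genes of the extracellular matrix and its proteases, 19 were higher and 0 lower (19 and 1 adjusted over the list alone), including COL4A1 (2.15 ± 0.14) and fibronectin (FN1, 2.27 ± 0.12). Of 11 mesenchymal genes 9 were higher and 1 lower (9 and 1 adjusted over the list alone), among them the receptor kinase AXL (1.64 ± 0.12) and the transcription factor SNAI2 (0.90 ± 0.19). Of 13 TGF-beta targets 10 were higher (11 adjusted over the list alone), with INHBA at 2.13 ± 0.16 and THBS1, an inhibitor of angiogenesis also on the tumour suppressor list, at 1.71 ± 0.13. Integrins were higher for 7 of 17 (8 adjusted over the list alone), led by ITGB1 and ITGAV, and tumour suppressors for 11 of 28, with 2 lower (11 and 3 adjusted over the list alone).

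Hypoxia and glycolysis genes were higher in RWPE2 for 13 of 29 and lower for 0 (16 and 1 adjusted over the list alone), with P4HA1 at 1.62 ± 0.18 and BNIP3 at 1.32 ± 0.14. ER stress genes were higher for 14 of 27 (17 adjusted over the list alone), with HERPUD1 at 2.19 ± 0.13, STC2 at 1.77 ± 0.13 and PDIA4 at 1.41 ± 0.13. The respiratory chain list went mostly the other way, with 10 of 44 lower and 3 higher (11 and 3 adjusted over the list alone), including NDUFA8 (-0.85 ± 0.12) and COX5B (-0.72 ± 0.13). Of 15 NF-kB and inflammatory genes 6 were lower and 2 higher (7 and 3 adjusted over the list alone), with the iron-binding LCN2 at -1.96 ± 0.12 and TNFAIP3 at 1.14 ± 0.12. Of 21 NRF2 genes 7 were lower and 2 higher (8 and 2 adjusted over the list alone), AKR1C1 among them at -0.94 ± 0.13. Immediate-early genes were split, with 6 of 17 higher and 5 lower (8 and 5 adjusted over the list alone), led by CCN1 (1.81 ± 0.13) and DUSP1 (1.81 ± 0.12). Desmosome and adherens junction genes were split too, with 6 of 17 higher and 3 lower (7 and 4 adjusted over the list alone), DSG2 at 1.61 ± 0.12 and PKP1 at -1.39 ± 0.12. Of the RAS-ERK list 5 of 22 were higher and 1 lower (5 and 1 adjusted over the list alone). In the untreated pair 13 of 32 lists stood apart, 9 higher and 4 lower. In the treated pair, a comparison added after the data had been seen, 7 stood higher and 7 lower. There desmosomes (percentile 83.0) and immediate-early genes (96.1) no longer stood apart, and DNA replication (0.310), histones (2.25) and the proteasome (2.06) stood lower. The call was lost under at least 1 alternative for NRF2 genes (percentile up to 33.3), integrins (down to 94.8), inflammatory genes (32.7 without a filter) and immediate-early genes (down to 48.5, with the sign of the median turned without a filter and with s and x probe sets left out).

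The genes higher with lunasin in RWPE1 were compared with the line difference, since both use the untreated RWPE1 array. Of the 48 genes, 38 were also at least 2-fold higher in untreated RWPE2 cells, where independent lists would share 2.57. Their median was 1.36 in the untreated line difference, 0.24 in the treated line difference and 0.04 for lunasin in RWPE2. Across genes the RWPE1 response and the untreated line difference had a correlation of 0.64. Simulated arrays with no effect that share the control and have equal noise gave 0.50. Equal noise gives that value at any noise size, so 0.50 cannot say how much of the overlap the shared control makes. The covariance was 0.11 in the data and 0.005 in the simulation, where the noise SD of 0.07 per array came from the RWPE2 pair. A noisier control would raise both simulated values. With 1 control array the shared control could not be split, and part of the overlap may come from it.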

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

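The tests of explanations in this part were chosen only after the results they bear on had been seen, and the test for RWPE2 RNA was widened, after it had been run, to all genes at least 4-fold higher in RWPE2. The test for noise was moved, after a first run on all genes, to the other probe sets of the genes in the pattern, and the test for scaling was replaced after a first run with renormalized arrays, whose outcome the data had fixed. Among 39 named genes looked at for changes of at least 0.2 in opposite directions, TMX1 and TWF1 were higher with lunasin in RWPE1 and lower in RWPE2. TMX1 was at 1.03 in RWPE1 and -0.23 in RWPE2, and TWF1 at 1.04 and -0.22, so RWPE1 makes up most of the difference. The responses differed by 1.26 and 1.26 on the log2 scale, a difference that was not tested. The other probe sets of TWF1 gave 0.44 and 0.23, and the other of TMX1 0.96. Among 3150 probe sets without a single gene name, which enter no comparison, 7 were at least 2-fold higher with lunasin in RWPE1 and 0 were lower, and 0 were 2-fold apart in RWPE2. On the untreated RWPE1 array the 18S ribosomal RNA control probe set was 1.28-fold, and the 28S control 1.35-fold, above the highest of the other 3 arrays.

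In RWPE1, 48 genes were at least 2-fold higher with lunasin and 0 lower, and 38 of them were also at least 2-fold higher in untreated RWPE2 cells. Array scaling or an intensity trend would move genes of like intensity alike. Set against the median of the 200 genes nearest in intensity, 83.3% of genes at least 1 SD away were higher (1143 against 229). That lies between the limits of 75% and 90% written for it, so by these limits the result is undecided. The comparison takes out any shift shared by genes of like intensity, however. The imbalance that remained thus argues against scaling or an intensity trend as its whole cause. For the 48 genes themselves the values of their neighbours argue against it. These had medians from -0.12 to 0.35, short of a 2-fold difference. Each of the 48 stayed at least 0.69 above its neighbours, but the choice of genes at least 2-fold higher largely sets that. For the 28 genes with another probe set the values argue against noise of single probe sets as the whole cause, since the other probe sets had a median difference of 0.35 (quartiles 0.15 and 0.71, percentile 100 of matched random genes). Of these 28, 20 had every other probe set above 0 and 13 had another at least 1.5-fold higher, so noise stays open for single genes. The other 20 genes have no other probe set, and there noise cannot be told apart from a difference. Loss of RNA from the 5 prime end would raise the 3 prime to 5 prime difference on the untreated RWPE1 array, yet it was the lowest of the 4 arrays for GAPDH (0.47, the next 0.54) and for ACTB (-0.47, the next -0.45). RWPE2 RNA in the treated RWPE1 sample would need a like share for every gene. All 40 genes at least 4-fold higher in RWPE2, 6 of them in the pattern, needed a median of 11.04% (upper quartile 18.1%). The 38 genes needed 65.2% (lower quartile 49.1%), but they were chosen for a 2-fold rise, which by itself sets a high share. The 40 were not chosen on the treated array, and their lower share argues against RWPE2 RNA as the whole cause of the pattern. A smaller share must also be alike for every gene. LOXL2 had intensities of 61.15 and 60.57 in untreated and treated RWPE1 and 500.4 in untreated RWPE2, and TMEM158 98.47, 86.36 and 586.1. CCN2 and SPARC rose by 0.09 and 0.13 on the log2 scale, and PLOD2 by 0.04, or 0.68 at its other probe set. The other genes named as furthest higher in untreated RWPE2 rose by 0.47 (FERMT2) to 1.65 (TPR). The genes that barely moved argue against a share large enough to make much of the pattern. A trace stays open. A response of RWPE1 cells to lunasin and an untreated RWPE1 array that stands apart for another reason cannot be told apart with 1 array per condition: either may leave these genes at similar levels on the other 3 arrays, and the median treated line difference of the 48 was 0.24.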

How the results depend on the processing

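The treated pair in place of the untreated pair was chosen after the data had been seen, and the other alternatives were planned. Of the counts and correlations 102 alternatives stayed within 1.5 times or the spread and 28 moved. Of list medians 656 stayed, 94 moved and 3 were counted as reversed, and of named genes 494 stayed, 74 moved and 1 became significant. The 3 do not hold every sign turn of a median near 0, such as those of DNA repair in RWPE1 with a common median and cyclic loess. For lunasin in RWPE1 the 48 higher genes became 16 with the upper-quartile filter, 22 with log2 of the intensity plus 16 and 433 at 1.5-fold, and 0 were lower in each. For lunasin in RWPE2 the 1 higher gene became 0 with the upper-quartile filter, with the median over probe sets and with s and x probe sets left out, and 2 at 1.5-fold. Between the untreated lines the 320 higher genes became 176 with the upper-quartile filter, 836 at 1.5-fold and 136 in the treated pair, and the 64 lower genes became 38, 39 with s and x probe sets left out and 365 at 1.5-fold. For the difference of the responses the 51 genes became 78 without a filter, 19 with the upper-quartile filter, 29 with the added 16 and 457 at 1.5-fold. The 1 gene with the larger RWPE2 response became 0 under cyclic loess, the upper-quartile filter, the median over probe sets, s and x probe sets left out and the added 16, and 14 at 1.5-fold.

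For the common lunasin effect limma called 21 higher genes after quantile normalization and 0 under every other alternative run. In that fit the prior degrees of freedom were infinite, so all genes shared a single variance, and the 21 had a median of 1.25 in RWPE1 and 0.12 in RWPE2, with 3 below 0 there. For the line effect 750 higher genes became 452 with the upper-quartile filter and 290 with s and x probe sets left out, where fewer genes are tested, and 567 lower genes became 373 under cyclic loess and 172 with s and x probe sets left out. Without a replicate block, limma gave 541 and 548 genes for the line effect in a model without the treatment term, and 0 for lunasin in a model without the line term. The immediate-early list between the lines changed from 0.29 to -0.051 without a filter and -0.10 with s and x probe sets left out, and the NF-kB list in RWPE1 from -0.17 to 0.092 with the upper-quartile filter. Filters and thresholds change which genes are counted, and for cyclic loess, the median over probe sets and the sign changes the cause was not tested. Leaving out an array was not possible, as each condition has 1 array and the model then has no residual degrees of freedom. With 1 array per condition, no paired analysis was possible beyond the pairing by line in the limma model. Signal near background limits dim genes, which the added 16 shrinks most.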

Other observations

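The tests of fibroblast genes and of ATF4 targets in this part were chosen only after the results they bear on had been seen. The test of aminoacyl-tRNA synthetases was written down before its value was computed. Single genes of groups that did not stand apart in the untreated pair also differed between the lines. KRT8, a keratin of simple and luminal epithelium, was higher in RWPE2 (0.93 ± 0.12 on the log2 scale, SE, n = 2 arrays per line, limma adjusted p = 0.00266), and the basal keratin KRT15 was lower (-1.47 ± 0.13, adjusted p = 0.000473). Their lists went both ways by the limma test, with 3 of 11 basal markers higher and 3 lower, and 1 of 7 luminal markers higher and 1 lower (4 and 3, and 1 and 1, adjusted over the list alone). The repair enzyme PARP1 was lower in RWPE2 (-1.21 ± 0.12, adjusted p = 0.000847), while of 24 DNA repair genes 2 were lower and 2 higher (2 and 0 adjusted over the list alone). Of 33 genes of DNA replication 7 were lower, among them MCM2 and RPA1, with 1 higher (8 and 2 adjusted over the list alone). Interferon-stimulated genes were split, with IFITM1 higher (1.42 ± 0.12) and BST2 lower (-1.03 ± 0.15).

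Mesenchymal and matrix genes were higher in RWPE2, and fibroblasts among the cells were weighed as a possible source. COL1A1, COL1A2, COL3A1, DCN and LUM, abundant in fibroblasts, had a median RWPE2 minus RWPE1 difference of -0.16 in the untreated pair and -0.01 in the treated pair. COL1A1 had intensities of 203.5 and 212.1 in the untreated lines. COL1A2, COL3A1, DCN and LUM lay below the filter intensity of 93.9 on every array, so the median rests largely on dim signal. These genes gave no sign of fibroblasts in RWPE2, but dim signal limits what they can show. The fixed stromal list went the other way, with a median of 0.24 in the untreated pair and 0.35 in the treated pair. It had 4 of 17 members kept, COL1A1 among them, too few for a percentile. By the limma test 2 members were higher in RWPE2, FBLN1 (0.67 ± 0.12) and MMP2 (0.50 ± 0.13), and 0 were lower. Fibroblasts as a source are therefore left undecided. The transformation of RWPE2 stays open as an explanation too and was not tested.

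TRIB3, CHAC1, PCK2 and VARS1, known targets of the stress factor ATF4, were lower with lunasin in both lines, although none passed the limma test, and a lower ATF4 program is a hypothesis for that. The median of 19 other ATF4 targets, 12 of them on a list already summarised, lay at percentile 53.9 of matched random lists in RWPE1 and 8.25 in RWPE2, and 7 members were below 0 in both. The limit first written for counting against the hypothesis was percentile 50, which this value passes; it was raised to 84 after the value had been seen, because 53.9 lies within the spread of random lists, so the result is left undecided, and under the first limit it would have counted against the hypothesis. The planned ER stress and ATF4 list ran the other way in RWPE1, with 18 of 27 above 0 (median 0.08, percentile 94.8), and lay at percentile 14.3 in RWPE2. Split after that was seen, its 10 folding and ER sensor genes lay at percentiles 96.3 and 99.9 in RWPE1 and RWPE2, and its 17 ATF4 genes, TRIB3 and CHAC1 among them, at 66.3 and 0. The median of 11 other aminoacyl-tRNA synthetases lay at percentile 94.8 in RWPE1 and 9.42 in RWPE2, which argues against a lower set of synthetases in both lines under either limit.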
